A study of Eohaustorius estuarius with 18 samples.

How the data were processed

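RNA from whole bodies of control and exposed amphipods was labelled with the dye Cy3 and hybridised to 18 single-colour Agilent arrays, 1 sample per array, per the labels' protocols. The scanner files hold spot intensity: per the file headers the authors quantified each scan with Agilent Feature Extraction under protocol GE1-v5_10_Apr08, which subtracts background and corrects spatial trends, and deposited the processed signal of each spot on a linear scale with no scaling between arrays. The headers give 10.1.1.1 as the version of the software's modules, whereas the submitters' processing notes give 9.1. The authors also deposited a table of log2 values for 8567 probes, of which 60 are control probes and 8507 match the arrays' probes. How that table was made is not given in the sources used here. Set against the scanner values, each of its columns matched quantile-normalised log2 signal centred on each probe's median over the arrays (r from 0.993 to 1.00, slope from 0.995 to 1.01), so its scale and direction are settled by that match and its tool is unknown. Column medians of that table lay between -0.04 and 0.03 except for control extract 5, at 0.28. No column of other samples was left aside.

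Groups and extract numbers came from the labels. Arrays named as repeats of 1 extract were averaged, so 8 extracts stood against 8. The labels do not say whether a shared number ties a control extract to a cyfluthrin extract, so numbers were not used as pairs. An extract stood for the animals in it; the p-values measure the spread between extracts of 1 exposure and cover no repeat of the exposure.

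Each array held 15744 spots, 15208 of them not controls, for 8507 probes of 60 bases. Control spots and spots flagged as outliers were left out, log2 of the processed signal was averaged over the spots of a probe, and each array's 75th percentile was subtracted. A probe was detected on an array when at least 50% of its spots were well above background, and it was tested if detected in at least 4 of the 8 extracts of a group, which left 7720 probes and 8 missing values. Differences were tested with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Where a probe was not well above background on any array of a group, a fold is given as at least N-fold, from the brighter group's mean against the dimmer group's mean of the higher of its own signal and each array's lowest signal well above background. Names came from the array files: 3137 probes had an informative name, and 2937 of these were tested. The pattern that decides which names are informative was loosened after the names were seen and before the probes to be named were picked by rule.

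Gene lists were 24 sets of name patterns fixed before the data were examined, of which 23 had the 5 tested probes required. They were tested with limma's camera at a preset correlation of 0.01, computed from moderated t so that probes with missing values stay in, which moved no list's p by more than 0.0702 on the log2 scale. Separation of the groups was tested by an exact permutation test of the mean distance between groups minus that within groups. The rule for named probes, fixed before the data were examined, took 1 probe per informative name: the 12 largest rises and 12 largest falls past the threshold, and for each list up to 4 members with the smallest p. Probes named beyond it were chosen after their values were seen. Among them are the further contigs of a shared name, heat shock protein 90 contig 5659, l2efl, alveolin, hsp20, elastase 4, xylanase and cysteine protease. Orf16-lacz fusion protein, membrane skeletal protein, involucrin repeat-containing protein, 26s protease subunit 4 and thyroid hormone receptor interactor 12 are others. The rest are hexokinase contig 7050, c-type lectin contig 6994 and those of the closing section's first paragraphs.

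Alternatives fixed before the data were examined covered background correction (normexp with offset 50), scaling (quantile, median, percentile over probes detected on all arrays), filters, treatment of repeat arrays, the authors' table, batch and replicate blocks, variance models, outlier flags, thresholds, set tests and leaving out each extract. Added afterwards were leaving out the dim centre of the array of control extract 5, leaving out cyfluthrin extracts 1, 5 and 6, both together, and leaving out the covarying risers. The dim area was found as a running median over 9 by 9 spots below -1 on the log2 scale, the only setting tried. The limit of 2 for the covarying risers and the r of 0.8 used to look for further probes like them were also set after the data were seen.

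The steps were tested on simulated data with 200 of the 7720 probes changed in the comparison of cyfluthrin with control. The test recovered 18% of the probes changed by 0.5 on the log2 scale, 64% at 1, 94% at 2 and 100% at 3, with 6 false among 144 calls. The simulated noise was independent between probes and was drawn on scaled, filtered values with no dim area. Probes that vary together or a damaged array can therefore give other rates in the real data. A darkened area of 1337 simulated spots was found to 98.4%.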

Results

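Whole-body RNA of Eohaustorius estuarius, a burrowing estuarine amphipod used in sediment toxicity tests, was compared after 10 days in sediment spiked with cyfluthrin at a nominal 1.6 μg/kg and in sediment spiked with solvent only. Cyfluthrin is a pyrethroid, a class of insecticide that acts on voltage-gated sodium channels of nerve cells. The extracts belong to a study of how well laboratories match when they run the same material on microarrays. The arrays described here came from its laboratory E, and those of the other laboratories were not analysed here. Labels gave 8 control and 8 cyfluthrin extracts on 18 arrays, since control extract 3 and cyfluthrin extract 5 were each run on 2 arrays. Each array held 8507 probes built on assembled transcript contigs of the amphipod, of which 3525 carried a name taken from similar proteins of other species. Names below are those similarity names, with a contig number in places where several contigs share one. A name given without a number may still belong to further contigs. No genome was at hand, so positions of the genes are not given.

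Between 68.6% and 94.6% of the spots on an array were well above background, and the lowest share belonged to the array of control extract 5. The 75th percentile of signal ranged from 334 to 735 units. The array of control extract 5 had a dim oval in its centre that covered 2591 spots, or 17.0% of those on the array, with a median log2 deficit of -2.47. No such area was found on the other arrays. Spike-in RNA gave a mean log2 signal of 8.23 to 9.04 on the arrays of cyfluthrin extracts 1, 5 and 6, and 9.44 to 11.70 on all others. The number of arrays limits the precision of every value below.

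**Figure D1:**
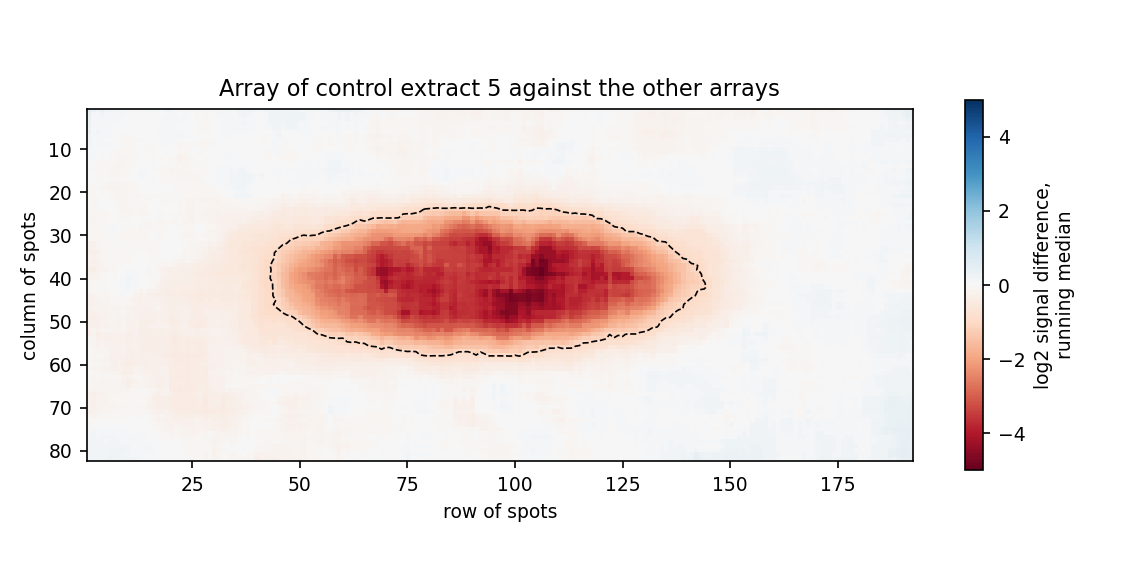
Map of the array of control extract 5, with rows of spots on the x axis and columns of spots on the y axis; colour is the running median of the log2 signal difference from the other arrays, and the dashed line encloses values below -1. The enclosed oval holds 2591 spots with a median deficit of -2.47.

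The main question was which transcripts differed between exposed and control animals. The largest rises among named probes were in those for rad50 (3.97), a translation elongation factor-like protein (3.91) and heat shock protein 90 (contig 5659, 3.86). A 60s ribosomal protein gave 3.81, lost with normexp. Its rank is uncertain, as it was well above background on 2 of the 9 control arrays. The largest falls were in cuticular protein 144, a haemocyanin, heat shock protein 70 and digestive enzymes such as trypsin. As lists fixed in advance, cuticle and chitin, digestive enzymes and hemocyanin were lower, calls that were lost with an estimated correlation (adjusted p = 0.519, 0.422 and 0.422). Among 7720 probes tested, 204 passed an adjusted p of 0.05 in limma, 99 of them higher and 105 lower in cyfluthrin extracts. The largest rise was 3.97 on the log2 scale and the largest fall was -2.51. Rises over 4-fold were estimated for 33 probes and falls over 4-fold for 5. Of those 33, 2 were not well above background on any control array, and 1 of these was at least 3.32-fold higher by the bound. Profiles of one group lay nearer to each other than to the other group by 6.37 units of Euclidean distance (one-sided exact permutation p = 0.0103 over 12870 splits). With the spots of the dim oval left out, a setting added after the data were examined, 370 probes passed, 185 in each direction, and 203 of the 204 were among them. The order of the largest changes shifted there. The 60s ribosomal protein (3.88) and heat shock protein 90 contig 5659 (3.86) stood above rad50 (3.73) and the elongation factor-like protein (3.66). Heat shock protein 70 contig 2561 gave -2.53 (limma adjusted p = 1.29e-07) and cuticular protein 144 gave -2.44. With the spike-in-poor cyfluthrin extracts 1, 5 and 6 left out, which leaves fewer extracts to compare, 142 passed and 118 were shared. With those extracts and the dim oval both left out, 285 passed and 167 were shared. With another background correction (normexp), 72 passed and 65 were shared, and the separation of the groups was no longer past its threshold (exact permutation p = 0.156).

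**Figure D2:**
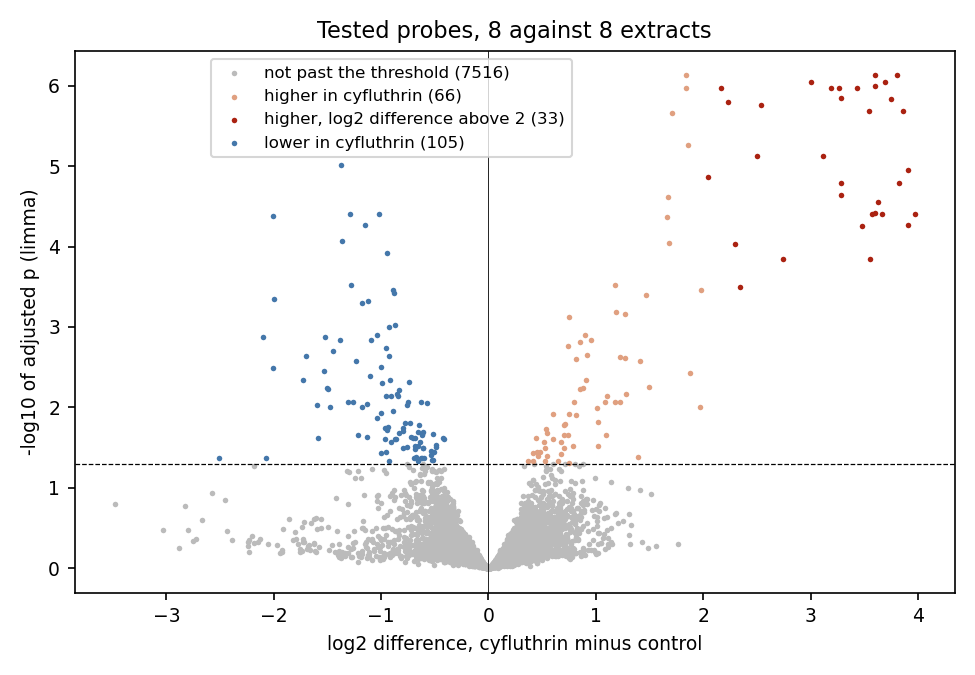
Each point is a tested probe, with the log2 difference of cyfluthrin minus control on the x axis and -log10 of the adjusted p from limma on the y axis; the dashed line marks an adjusted p of 0.05. The 33 probes with an estimated rise above 2 on the log2 scale lie on the right, with further higher probes just under that limit. Of the 33, 2 were not well above background on any control array. The 105 lower probes reach -2.51.

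Heat shock protein 90 (contig 4879), a chaperone of signalling proteins, went from -1.44 ± 0.58 (SD, n = 8) in controls to 2.26 ± 0.66 (n = 8) in cyfluthrin extracts, in log2 units relative to the array's 75th percentile, a rise of 3.70 (SE 0.29, limma adjusted p = 8.91e-07). A second heat shock protein 90 contig (5659) rose by 3.86, heat shock protein 83-1 by 3.27, the co-chaperone p23 by 3.74 and a protein of the stress-seventy family by 3.60. Actin (contig 4390) rose by 3.54, glyceraldehyde 3-phosphate, listed with the glycolytic enzymes, by 3.19 and fructose bisphosphate aldolase by 2.54. The translation elongation factor-like protein (contig 4158) rose by 3.91, a probe named for the DNA repair protein rad50 by 3.97 and an alkyl hydroperoxide reductase, an antioxidant enzyme, by 3.29. Further large rises carried the names myeloid leukemia (3.43) and SH2 domain-containing protein (3.28). A 60s ribosomal protein rose by 3.81, although it was well above background on 2 of the 9 control arrays and its call was lost with normexp (0.76, adjusted p = 0.665).

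All of these belonged to a set of 33 probes with rises above 2 (a limit chosen after the values were seen, with no gap there: 2.04 inside and 1.98 outside), of which 20 had a name. Their median rise was 3.48, and the mean level of the set was higher in each of the 8 cyfluthrin extracts (2.46 to 3.92 above the control mean) than in any control extract (-1.07 to 1.22). Of the 33 members, 2 were not well above background on any control array. For 1 of these, membrane skeletal protein, the bound was at least 3.32-fold, which alone does not place it past the limit. Over the 29 members with a value in every extract once the dim oval was left out, deviations from the group means had a median pairwise r of 0.773. Random sets of 29 probes matched on signal gave -0.0605 to 0.161. Outside the set, 12 tested probes shared a name with a member and had a median of -0.17, a value that the limit of 2 itself keeps low. Among them, heat shock protein 90 contig 8482 rose and contig 6339 gave -1.24 (adjusted p = 0.0758, but 0.00699 with the dim oval left out). Limma called 33 of 33 members with quantile, median and the other percentile scaling, and 26 with normexp, where the median was 2.13 and the lowest member -0.06. Whether these transcripts came from the amphipods or from another organism in or on them was not traced.

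**Figure D3:**
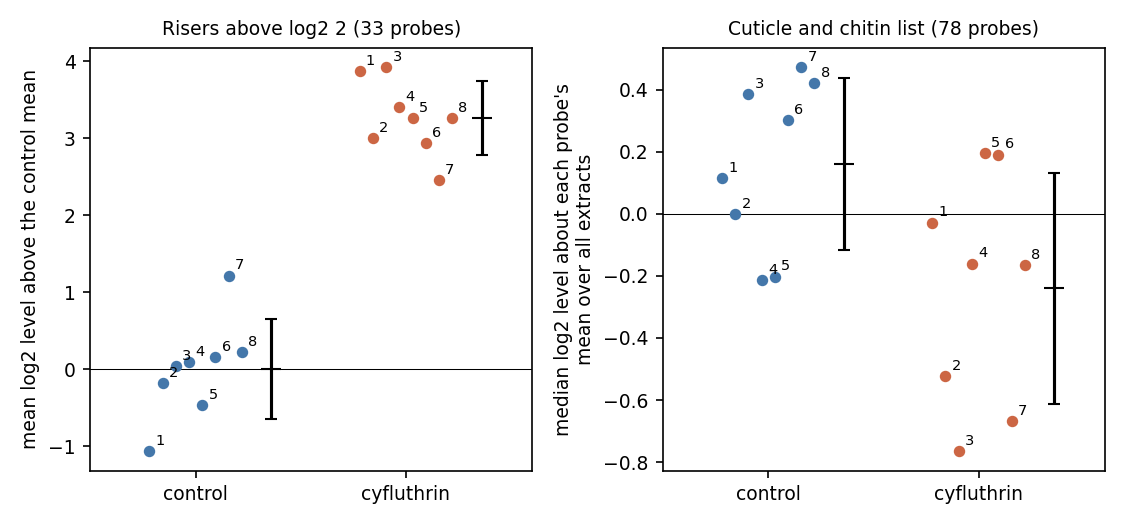
Levels per extract of the 33 probes with rises above 2 (left, mean log2 level above the control mean) and of the 78 cuticle and chitin probes (right, median log2 level about each probe's mean over all extracts); points are extracts with their numbers, bars are the mean and SD of 8 extracts. The groups do not overlap on the left (2.46 to 3.92 against -1.07 to 1.22) and overlap on the right.

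Of 71 tested probes for heat shock proteins and chaperones, which help proteins fold, 7 rose, 4 fell and 60 did not pass; adjusted over the list alone, 9 rose and 10 fell. With the dim oval left out, 7 rose and 9 fell. Of the 7 that rose, 4 belonged to the covarying set of 33. Falls concerned 3 contigs of heat shock protein 70, namely 2088 (-2.01, SE 0.24, adjusted p = 4.14e-05), 2561 (-2.10) and 2087 (-2.01), as well as a small heat shock protein (-1.37, SE 0.14, adjusted p = 9.81e-06). Heat shock protein 70 contigs 4070 (-0.64), 2089 (-0.42) and 2086 (-0.16) did not pass, and the last was the brightest of that name in controls. The brightest heat shock protein 90 contig in controls (1253) gave -0.30 and did not pass either. Another heat shock protein 70 contig (52) rose by 1.23, being well above background on 3 of the 9 control arrays. Heat shock protein 90 contig 8482 was at least 2.15-fold higher, being not well above background on any control array. Both probes, and an hsp20 family protein that rose by 0.70, turned slightly negative with normexp (-0.26, -0.14 and -0.03). None of these values passed, and the median of all tested probes shifted by -0.18 in that setting. The protein l2efl, related to small heat shock proteins, rose by 0.85; its name and that of the stress-seventy family protein matched no pattern of the list. As a list the chaperones did not pass (adjusted p = 0.437; median -0.08, mean 0.05).

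**Figure D4:**
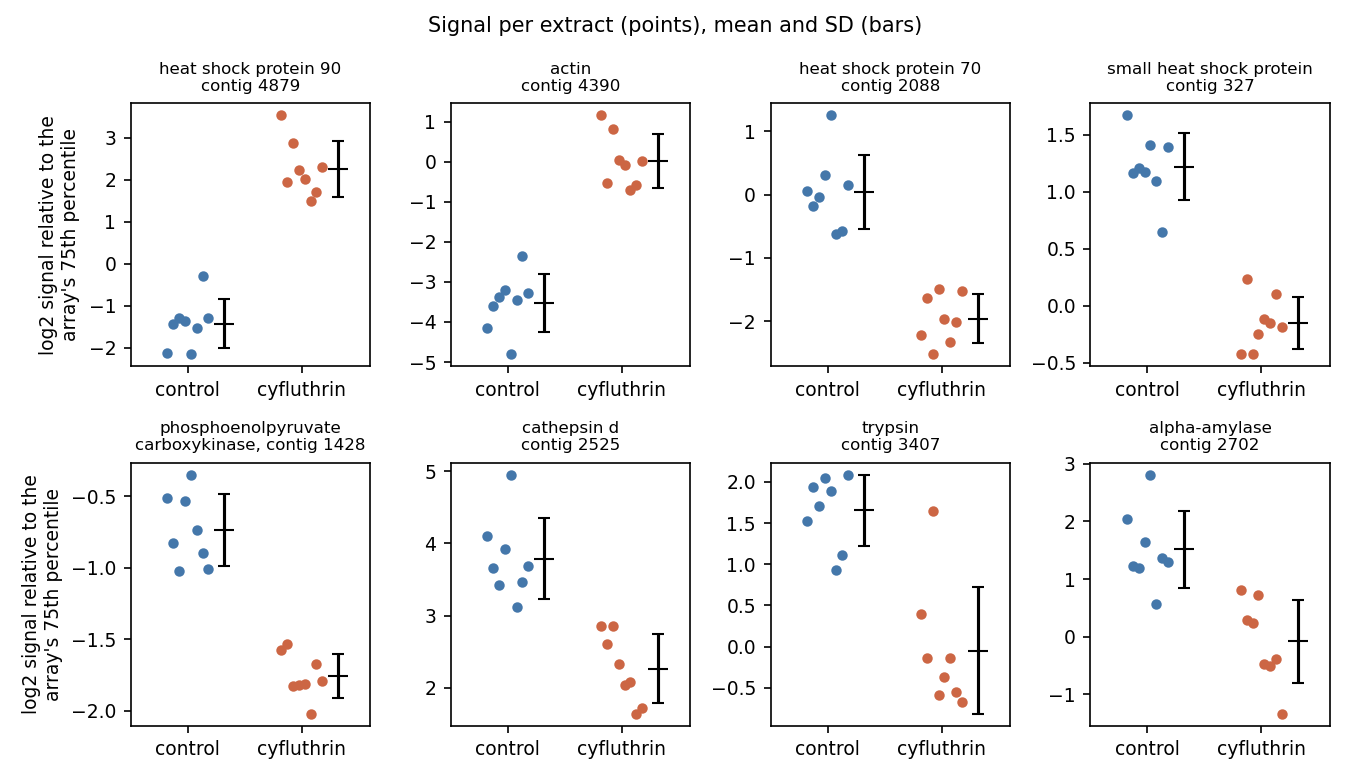
Log2 signal relative to the array's 75th percentile on the y axis for 8 named probes in control and cyfluthrin extracts; points are extracts, bars are the mean and SD of 8. Heat shock protein 90 and actin rose by 3.70 and 3.54, and the other 6 probes fell by between 1.02 and 2.01.

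Digestive enzymes were lower as a list (75 probes, median -0.18, mean -0.24, camera adjusted p = 4.42e-04), with 9 falling, none rising and 66 not passing; adjusted over the list alone, 17 fell and 2 rose. With the dim oval left out, 14 fell and 1 rose. The call was lost with an estimated correlation (adjusted p = 0.422 with an estimated correlation). Trypsin, a gut protease, fell by 1.70 (SE 0.29, adjusted p = 0.00228), serine protease 42 by 1.54 and cathepsin d (contig 2525), a lysosomal and gut protease, by 1.53. Another cathepsin d contig (2587) gave -0.28 (limma adjusted p = 0.642, but 0.00658 with the dim oval left out). The starch-digesting alpha-amylase fell by 1.60 (contig 2702) and 1.22 (contig 833), and another alpha-amylase contig (7371) gave -0.83 without passing. Amyrel, a relative of amylase, fell by 1.45 outside the list, while carboxypeptidase b2 fell by 1.24 within it. Other enzymes outside the list rose, namely elastase 4 precursor by 0.81 (adjusted p = 0.0124, -0.05 with normexp) and, in the covarying set, a cysteine protease by 3.12. A probe named for a xylanase rose by 1.39 (lost with median scaling, and -0.19 with normexp). It was well above background on 1 of the 9 control arrays. Within slides the list's median was -0.35, -0.28, -0.19 and 0.02, and with slide as a block it was -0.19. Serine protease 42, amyrel and alpha-amylase contig 833 lost their calls with normexp (adjusted p = 0.264 and 0.313 for the first pair).

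The cuticle and chitin list, which holds structural proteins of the exoskeleton and chitin-degrading enzymes, was lower too (78 probes, median -0.39, mean -0.58, camera adjusted p = 3.16e-05). Lower values were seen for 69 of its members, but 3 fell past the threshold, over all probes and adjusted over the list alone, and none rose; with the dim oval left out, 3 fell and 1 rose. Its call was lost with an estimated correlation (adjusted p = 0.519 with an estimated correlation). The 3 were cuticular protein 144 (contig 2742, -2.51, SE 0.64, adjusted p = 0.0426), midgut chitinase (-0.87) and chitinase 1 precursor (-0.83). The first of them lost its call when single extracts were left out, in 12 of 16 cases, and midgut chitinase in 6 of 16; all 3 lost theirs with normexp (adjusted p = 0.179, 0.0870 and 0.552), and both chitinases without cyfluthrin extracts 1, 5 and 6. Another contig of cuticular protein 144 (2980) gave -0.44 and did not pass. Within slides the list's median lay between -0.66 and -0.31, and with slide as a block it was -0.40. The extracts of both groups overlapped.

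Hemocyanin, the oxygen carrier of the hemolymph, had 6 probes, all with lower values (median -0.51, mean -0.94, camera adjusted p = 0.00423; adjusted p = 0.422 with an estimated correlation). A hexameric haemocyanin (contig 356) fell by 2.07 (SE 0.52, adjusted p = 0.0421), a call lost in 13 of 16 cases when 1 extract was left out, with normexp, with median scaling, with slide as a block, with trend and robust variance and without cyfluthrin extracts 1, 5 and 6. Hemocyanin subunit 1 gave -2.18 (adjusted p = 0.0531), and 2 of the 6 fell adjusted over the list alone or with the dim oval left out. Within slides the list's median lay between -1.41 and -0.18, and with slide as a block it was -0.59.

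Glycolysis and energy buffering had 13 probes, with 2 rising and 4 falling; adjusted over the list alone 3 rose and 5 fell, and with the dim oval left out 2 rose and 5 fell. Both risers belonged to the covarying set. Hexokinase a, which phosphorylates glucose, fell by 1.39 (SE 0.23, adjusted p = 0.00147), another hexokinase (contig 7050) by 1.18 and phosphoenolpyruvate carboxykinase, an enzyme of glucose synthesis, by 1.02 (contig 1428, SE 0.12, adjusted p = 3.98e-05) and 0.87 (contig 5309, lost with normexp at an adjusted p of 0.370). The list did not pass (adjusted p = 0.437; median -0.49, mean 0.08).

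Among 38 probes for cytochrome P450 and carboxylesterase enzymes, which open the breakdown of foreign compounds, 2 fell and none rose, over all probes and adjusted over the list alone (list adjusted p = 0.437). With the dim oval left out, 4 fell. A cytochrome p450 (contig 2661) fell by 0.64 (adjusted p = 0.0167) and aldehyde dehydrogenase 7 member a1 by 0.65 (adjusted p = 0.0304), the latter losing its call in 8 of 16 cases when 1 extract was left out. No member passed among 14 conjugating enzymes (list adjusted p = 0.958) or 4 ABC transporters, a list too small to test. Of 27 antioxidant and metal-binding probes, catalase, which removes hydrogen peroxide, fell by 0.96 (adjusted p = 0.0179); adjusted over the list alone 2 fell and 1 rose, and with the dim oval left out 1 fell and 1 rose (list adjusted p = 0.920). The alkyl hydroperoxide reductase that rose by 3.29 matched no pattern of this list. The aldehyde dehydrogenase lost its call with median scaling and with the row of the array as a block too. Catalase, the cytochrome p450 and the aldehyde dehydrogenase lost their calls with normexp and without cyfluthrin extracts 1, 5 and 6.

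Voltage-gated sodium channels and other ion channels and pumps had 7 tested probes, 1 of which rose, over all probes and adjusted over the list alone (list adjusted p = 0.920). This was ligand-gated chloride channel homolog 3 (0.75, SE 0.16, adjusted p = 0.0123), whose call was lost with normexp and without cyfluthrin extracts 1, 5 and 6. None of 21 synapse and neurotransmission probes passed by either adjustment (list adjusted p = 0.958); the acetylcholinesterase precursor gave -0.39 (adjusted p = 0.331). With the dim oval left out, survival motor neuron protein rose by 0.50 (adjusted p = 0.0230). It entered the list through the letters neuro in its name, which do not show a role at the synapse.

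Among 60 immune probes 3 fell, and 4 fell and 1 rose when adjusted over the list alone (list adjusted p = 0.437), while 5 fell with the dim oval left out. Toll-like receptor, a pattern-recognition receptor, fell by 1.09 (adjusted p = 0.00147) and c-type lectin by 0.91 (contig 6994) and 0.72 (contig 1221), both lost with normexp and contig 1221 also without cyfluthrin extracts 1, 5 and 6. Laccase 1 (contig 2001), a copper oxidase in no list, fell by 1.31 (adjusted p = 0.00870), a call lost with normexp too. Another laccase 1 contig (7895) gave 0.07 and did not pass. Of 19 vitellogenin and lipid transport probes the very low-density lipoprotein receptor rose by 1.49 (adjusted p = 0.00555; list adjusted p = 0.321), a call lost with normexp. Muscle contractile proteins (70 probes, list adjusted p = 0.920) had actin contig 4390 rising and troponin c, the calcium sensor of muscle, falling by 0.70 (lost with normexp and without cyfluthrin extracts 1, 5 and 6); adjusted over the list alone, 1 rose and 2 fell, and with the dim oval left out 2 rose and 2 fell. In the mitochondrial respiratory chain (58 probes, list adjusted p = 0.117) nadh dehydrogenase fell by 0.80, a call lost without the same 3 extracts. The germ line list (16 probes, list adjusted p = 0.321) had 1 fall, early meiotic induction protein (-0.61, lost with normexp, with median scaling and without those extracts). Besides the members of the covarying set already given, no ribosomal protein (52 probes, list adjusted p = 0.196) or translation factor (57 probes, list adjusted p = 0.548) passed. No probe matched by the patterns passed for moult and hormone signalling (10, list adjusted p = 0.857), proteasome and ubiquitin (71, list adjusted p = 0.857), cell cycle and DNA repair (45, list adjusted p = 0.920) or apoptosis and stress signalling (18, list adjusted p = 0.958), although 1 moult probe fell when adjusted over the list alone or with the dim oval left out. With the oval left out, 1 further probe rose for ribosomal proteins and 1 for translation factors, and 1 rose for each of the proteasome and apoptosis lists. Outside these patterns, 26s protease regulatory subunit 4 of the proteasome fell by 0.80 (adjusted p = 0.0318, lost with normexp), thyroid hormone receptor interactor 12, a ubiquitin ligase, rose by 0.86 (lost with normexp) and the DNA repair probe rad50 rose as given above.

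A list meant as a sign of RNA quality, with patterns for ribosomal RNA, drew 21 probes (list adjusted p = 0.201). Except for 1 probe named ribosomal rna (-0.02), they were named for mitochondrial ribosomal proteins and rRNA processing or modification, and so do not measure RNA quality. The processing protein tsr2 rose by 0.68, a call lost with normexp, with median scaling and without cyfluthrin extracts 1, 5 and 6. A list for other organisms in or on the animals drew 17 probes, among them gag-pol polyproteins of mobile elements and 2 proteins named for chlorophyll, none of which passed (list adjusted p = 0.886). In 9 of the 23 lists tested, the median, the mean and the test differed in sign, none of them among the 3 that passed.

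**Figure D5:**
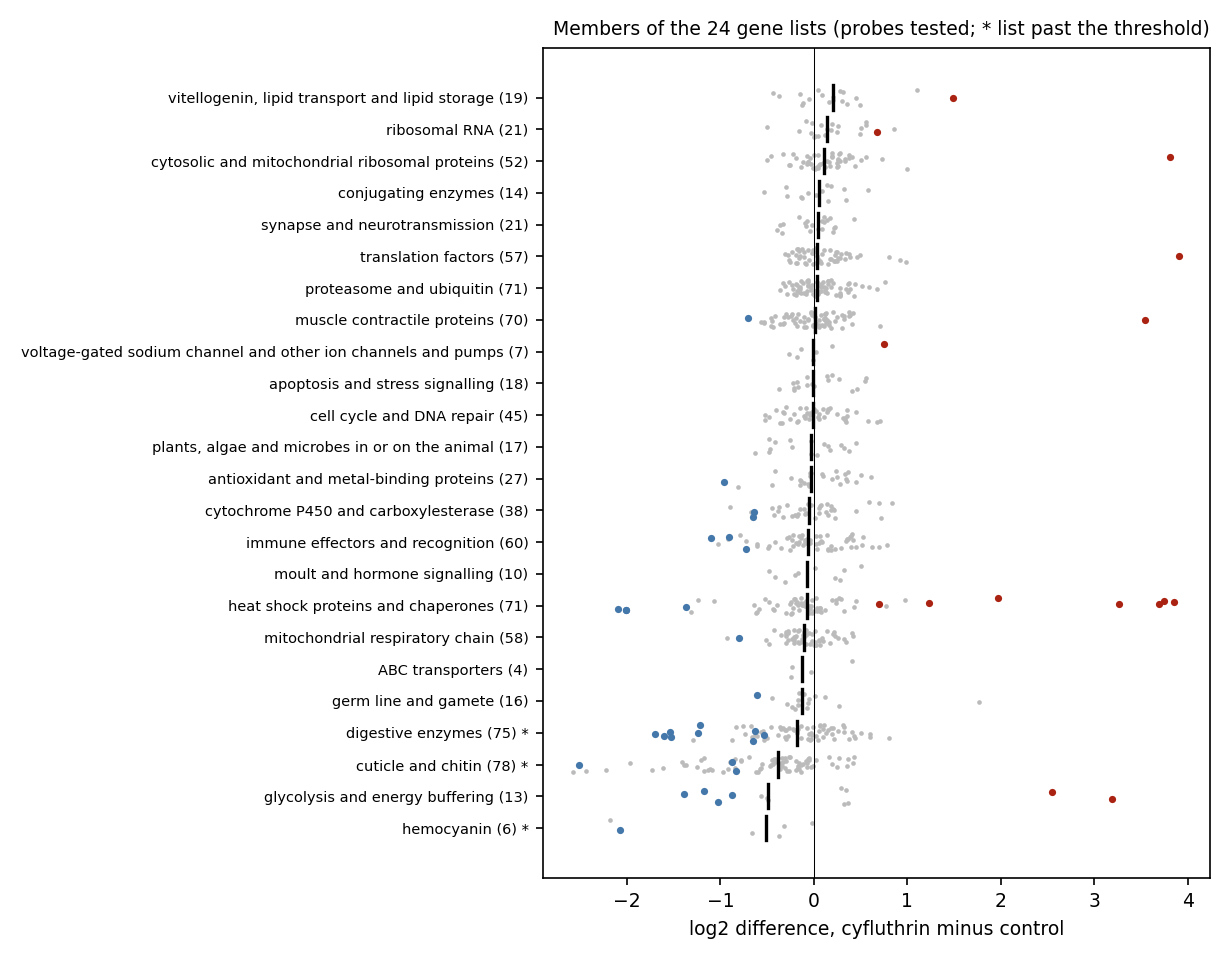
Log2 difference of cyfluthrin minus control (x axis) for the tested members of 24 gene lists, ordered by their median (black bar); red and blue points rose and fell past an adjusted p of 0.05, grey points did not pass, and an asterisk marks a list with a camera adjusted p under 0.05. The lists marked are cuticle and chitin (median -0.39), digestive enzymes (-0.18) and hemocyanin (-0.51).

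Each of the 4 slides and 3 scan dates held both groups. With slide as a block 196 probes passed, with scan date 211 and with the row of the array on its slide 193. The median of the 99 higher probes was 1.57, 1.29, 1.16 and 1.31 within slides 1 to 4, and that of the 105 lower probes was -0.88, -0.83, -1.10 and -0.71. The set of 33 gave 4.60, 2.74, 3.25 and 3.26, and 3.41 with slide as a block. Within the 3 scan dates it gave 3.26, 3.56 and 3.25. All these probes were picked by their difference over the same arrays, so their direction within slides and dates was largely fixed in advance. Among all 7720 tested probes, 65.6% to 77.1% had the same direction within a slide. Slide 1 held only 1 cyfluthrin array.

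The last comparison set repeat arrays of 1 extract against arrays of different extracts. The SD of the log2 difference over tested probes was 0.213 for the arrays of control extract 3 and 0.212 for those of cyfluthrin extract 5, with r of 0.996 and 0.995 across probes. Pairs of different extracts had a median SD of 0.718 (0.519 to 1.48) among controls and 0.775 (0.476 to 1.09) among cyfluthrin extracts. Without control extract 5 the median among controls was 0.671. Only 1 extract per group was repeated, so this is a description without a test.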

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

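Both tests on the array of control extract 5 were chosen after the result was seen, and they were redefined once after a first version had been run.

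Each of 98 sets of 8 extracts (named probes and array measures, per group) was searched for a single extract standing farther from the rest than Dixon's 95% limit allows, which chance alone does in about 1 of 20 sets. In 11 sets it happened, 7 times at control extract 5; the values below are the gap to the nearest extract as a share of the range. Heat shock protein 90 contig 4879 was highest in control extract 7 (0.536), the control extract with the highest level of the 33 covarying risers. In cyfluthrin extract 3, trypsin (0.539) and serine protease 42 (0.603) were highest. Control extract 5 was highest for hexokinase a (0.554), aldehyde dehydrogenase 7 member a1 (0.559), nadh dehydrogenase (0.648) and the processing protein tsr2 (0.542). With the dim oval left out, the cyfluthrin minus control differences of these probes all moved up. They went from -1.39 to -1.32, -0.65 to -0.58, -0.80 to -0.73 and 0.68 to 0.75, in that order. A shift this even points to that array's scaling value, lowered by the oval, for part of their height. They need not be separate observations, and whether they pass the limit without the oval was not tested. The array of control extract 5 also had the most outlier spots (51, gap 0.538), the lowest signal of a class of the array's own control probes (5.31 on the log2 scale, gap 0.854) and the lowest median correlation with its group (gap 0.757). The array of cyfluthrin extract 8 had the fewest outlier spots, 8 (gap 0.588).

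Control extract 5 correlated with the other controls at a median r of 0.837 across probes, and leaving out the dim centre of its array raised this to 0.933, with the other controls at 0.945 to 0.969. Inside the area r was 0.494 against 0.944 to 0.961 on the other control arrays, and 28 of the 36 spots of the control probe class that stood apart lay there. Over spots at least 10 rows or columns beyond the area r was still 0.932. This was below the lowest other control array (0.944) by more than their SD, the limit set for this test. The first version, over all spots outside the area, had come out the same way. The area thus accounts for most of the drop. Whether anything else sets this extract apart cannot be told, since some extract must be lowest. With the area left out, cyfluthrin extracts 1 and 3 had lower medians with their own group (0.921 and 0.916). A low labelling yield cannot be told apart from ordinary spread, because the spike-in signal far from the area (10.16 on the log2 scale) lay just under the lowest other control array (10.17), and the first version, without a margin (10.09 against 10.19), had counted that as low. No biological explanation was tested, since the labels give nothing that sets this extract apart.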

How the results depend on the processing

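Leaving out the dim centre, cyfluthrin extracts 1, 5 and 6, both together, or the covarying risers was chosen after the data were seen; all other settings were fixed before.

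None of the counts, the lists that passed, the separation or the probes named by rule reversed under the settings tried; some probes named beyond the rule did, with normexp. The count of probes differing between cyfluthrin and control (204), with 99 probes higher in cyfluthrin and 105 probes lower in cyfluthrin, moved by over 1.5 times under 5 settings besides leaving out single extracts. Normexp gave 72 (44 higher, 28 lower; 61.1% higher against 48.5%), shifted the median of all probes by -0.18 and ended the overall separation of the groups (3.86, exact permutation p = 0.156); the cause was not tested. Counting 18 arrays as separate samples gave 340 (161 and 179), which treats repeats as replicates. Array weights gave 505 (288 and 217), with a weight of 0.0865 for control extract 5, and leaving out the dim centre gave 370 (185 and 185). The replicate block, pairing extracts by number, gave 125 (65 and 60), 121 of them shared. Whether numbers pair extracts is not said in the labels. Deviations of same-numbered extracts correlated from -0.37 to 0.35, with 3 of 8 pairs over 0.1 and 1 pair a mutual best match, which does not settle it. The block left the lists at 3 and the separation at 10.3 (exact permutation p = 0.00781, the smallest value that 8 pairs allow). Over the settings that left out 1 extract, probes ranged from 162 to 346, higher probes from 83 to 184, lower probes from 76 to 162, lists from 3 to 4 and separation from 4.73 to 8.36 (p from 0.00528 to 0.0306). Each highest count came without control extract 5 (346, 184 and 162). Lists fell from 3 to 0 with an estimated correlation, which allows for members varying together, and came to 5 without the covarying risers; taking out members chosen for rising lowers the chaperone and glycolysis lists by construction, so these 2 additions are no result. Fry passed digestive enzymes (adjusted p = 0.0323) and hemocyanin (0.0435), both lower, and ribosomal proteins (0.0323) and the ribosomal RNA list (0.0139), both higher, but not cuticle and chitin (0.195); it does not compare a list with other probes. With 1 probe per name, cuticle and chitin and digestive enzymes passed and hemocyanin was too small to test. Without cyfluthrin extracts 1, 5 and 6 the separation was 8.69 (exact permutation p = 0.0490), and without the covarying risers 4.11 (p = 0.0353). No separation value exists for the random extract block, trend and robust variance or array weights, which change only the model of each probe.

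Of 39 named probes past the threshold, 21 kept their call under every setting that tested them. The setting of only probes above background in all 16 extracts tested 35 of the 39. Normexp ended 17 calls and median scaling 4 (haemocyanin contig 356, aldehyde dehydrogenase 7 member a1, early meiotic induction protein and tsr2). The replicate block ended 8, those 4 with the cytochrome p450, midgut chitinase, troponin c and nadh dehydrogenase. Leaving out cyfluthrin extracts 1, 5 and 6 ended 12, those 8 with catalase, chitinase 1 precursor, c-type lectin contig 1221 and the chloride channel. Leaving out these extracts and the dim centre together ended only 4. Losses without the 3 extracts therefore need not mean that a call rests on them. Trend and robust variance ended 2, cuticular protein 144 and haemocyanin contig 356. Leaving out 1 extract ended 7: cuticular protein 144 in 12 of 16 cases (all but control extracts 4 and 7 and cyfluthrin extracts 5 and 6; adjusted p up to 0.0935), haemocyanin contig 356 in 13 (all but control extract 6 and cyfluthrin extracts 2 and 3; up to 0.0907), aldehyde dehydrogenase 7 member a1 in 8 (up to 0.0671), tsr2 in 8 (up to 0.0626), midgut chitinase in 6 (up to 0.0573), c-type lectin contig 1221 in 2 (control extract 2, cyfluthrin extract 5; up to 0.0530) and troponin c in 1 (control extract 3; 0.0528). Of 96 called probes with an informative name, 36 kept their call with normexp and 12 changed direction. Those 12 lay between -0.28 and -0.02 there, none past the threshold, where the median of all probes shifted by -0.18. Signal near background limits what can be said of such dim probes.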

Other observations

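Tests of covariation, of a general rise and of the dim area on the cuticle list were chosen after the results were seen; those of base composition, slide and other splits of the extracts were written before.

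Beyond the lists, nattectin precursor, named for a lectin-like fish venom protein, rose by 1.84 (SE 0.16, limma adjusted p = 1.08e-06) and kept its call with normexp (1.79). Taurine dioxygenase fell by 1.18 and cysteine dioxygenase by 0.99, the latter a call lost with normexp (adjusted p = 0.0715). Sphingomyelin phosphodiesterase, which releases ceramide from membrane lipid, fell by 1.15 (contig 3482) and 0.94 (contig 4753, lost with normexp at an adjusted p of 0.415). A hemocyte transglutaminase, listed as hemocyte protein-glutamine gamma-, fell by 0.88 and hemolymph clottable protein by 0.93 (lost with normexp, adjusted p = 0.248, and with median scaling), both parts of crustacean clotting. Glutamine synthetase, which fixes ammonia, rose by 0.54 (lost with normexp at an adjusted p of 0.110). These probes were picked after their values were seen, as no list covered them; taurine dioxygenase, sphingomyelin phosphodiesterase contig 3482 and the transglutaminase kept their calls with normexp (adjusted p = 0.00533, 0.00260 and 0.0105).

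Among the 33 strong risers, the 29 with a value in every extract once the dim area was left out had a median pairwise r within groups of 0.773, above every one of 1000 signal-matched random sets of 29. A slide effect is argued against by the layout, as each slide held both groups. With slide as a block the set's median was 3.41. That value and the lowest median within a slide, 2.74, add little, since members were picked for their rise over the same arrays. For a general rise of chaperone and housekeeping transcripts, the 5 lists that hold a set member were taken whole. Over 287 probes, all their tested members with the set added, the median was 0.0361 (SD 1.15) against 3.48 in the set. Each list's median, from -0.49 to 0.11, lay 2.87 to 6.81 of its own SD below the set's. The limit of 2 keeps the set's median high, so that gap decides nothing. The list medians argue against a rise of most members of these lists, whereas a rise of some members stays open. This test replaced one on 12 same-name probes outside the set, whose outcome the limit of 2 had fixed. RNA of another organism, more of it in the cyfluthrin extracts, is a candidate source that the covariation leaves open. The name alveolin, a structural protein of alveolate protists, belongs to 1 member (2.17, lost with normexp). Further members were named orf16-lacz fusion protein (2.50, kept with normexp), membrane skeletal protein (at least 3.32-fold) and involucrin repeat-containing protein (at least 4.33-fold), the last pair lost with normexp. The source of these transcripts was not traced. A co-regulated group of the animal's own genes, as a response to exposure, would vary together in the same way and stays open, untested. Base composition cannot tell, since the set's median GC content of 41.7% lay on the edge of the middle 95% of 10000 random sets (41.7% to 45.0%, two-sided permutation p = 0.0423), and the rule that a tie decides nothing was added after this was seen. Of probes outside the set, 3 followed its profile within groups at r over 0.8 and 2 of these rose, where shuffled profiles gave a median of 0 and at most 13.

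The cuticle and chitin list was lower by a median of -0.39, and neither the dim area nor base composition is likely to be the cause: without the area's spots its adjusted p was 5.77e-05, and 0% of 1000 random lists matched on GC content and signal had a median as low (-0.12 to 0.11). Of its 78 members, the 73 with a value in every extract once the area was left out varied together within groups (median pairwise r 0.170, against 0.00301 to 0.145 in signal-matched random lists), which a preset correlation of 0.01 does not allow for, and the adjusted p with an estimated correlation was 0.519. The call may therefore reflect a few extracts that differ in the whole list, for instance in moult stage, as much as exposure; moult stage was not recorded in the labels and was not tested. An effect of exposure stays open.

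Grouping by chance was examined with 100 of the 6435 splits into 8 and 8, the real one included. For the number of probes passing, 1 of the 100 splits reached the real 204 and the highest other gave 36; for higher and for lower probes, 1 of 100 reached 99 and 1 of 100 reached 105, with 36 as the highest other, taken as the larger of a split's 2 directions since which side of a split is called exposed is arbitrary. That 36 came from 1 split, with 36 probes in one direction and 0 in the other. No other split drawn reached these counts, which makes chance unlikely for them without excluding it. With 100 splits the share can be no smaller than 1 in 100. The other splits also mix the groups, so the group difference adds to their spread and lowers their counts. For the gene lists 6 of the 100 splits gave 3 or more, the highest other being 3, so chance cannot be excluded for the number of lists.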
